A study of Mus musculus with 12 samples.

How the data were processed

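RNA was measured by sequencing in fully grown mouse oocytes at the germinal vesicle (GV) stage, the stage before meiosis resumes. The 12 libraries form 3 groups of 4, and each group was read from the sample titles. GT oocytes carry a gene trap in Marf1, GTWT oocytes are GT oocytes injected with mRNA for wild type MARF1, and GTD272 oocytes are GT oocytes injected with mRNA for MARF1 mutated at aspartate 272. Per the labels, each sample held 80 oocytes from C57BL/6 mice of 3 weeks primed with 5 IU of PMSG, a gonadotropin that makes follicles grow, for 46 h. Injected oocytes were cultured for 48 h with milrinone, a phosphodiesterase inhibitor that keeps oocytes at the GV stage. The labels do not say whether the GT oocytes were cultured or injected with a control RNA. Nor do they say that the samples of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. The labels differ on the starting material and on amplification: a protocol names lysed ovaries while the design names oocytes, and Smart-seq2 amplification is named beside an RNeasy Micro extraction.

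Per the labels, libraries were made with a NEBNext Ultra kit and read as 150 bp pairs on an Illumina HiSeq instrument. Per the submitters' processing notes and design text, trimmed reads were aligned to mm10 with TopHat2 2.0.13. The authors computed and normalized FPKM (fragments per kilobase of transcript scaled to the mapped fragments) with Cufflinks 2.2.1, per the labels. The p-values and q-values in the authors' deposited table come from Cuffdiff with default settings, per the labels, and the log2 fold changes in the deposited table are those of the same comparisons. The gene annotation the authors used is not given in the sources used here. Cufflinks divides reads that match several near-identical genes by an estimate, so members of multi-copy families are given as uncertain. No source used here says that strand was used, so overlapping genes cannot be told apart either.

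The deposited table holds 24254 genes. Its header names stood 1 column to the left of the values and were realigned. After this, the authors' log2 fold changes matched the log2 ratios of the mean FPKM with Pearson r of 0.9979 to 0.9987 across genes in the 3 comparisons. A spreadsheet had turned 27 gene symbols into dates, and these were left out of matching by name. Of the symbols, 24100 (99.4%) were found in RefSeq's annotation of GRCm38, the assembly of mm10, from which coordinates of named genes were taken. The table puts 5708 genes in a locus that holds another listed gene too, and 20 of the 116 named genes are among them, including Ppp2cb (with Ubxn8) and Zcchc18 (with Slc25a53).

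FPKM values carry no read counts, but low values showed the relative depth. Of 14432 pairs of low values, 93.6% were ratios of whole numbers up to 5 within 0.02 on the log2 scale. The relative depth obtained from these steps was 55.4% to 100% of the deepest library. FPKM of 1282 small RNA genes took 15.2% to 84.0% of a library's FPKM sum, and without them the sums were 400611 to 416754.

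The test was limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(FPKM + 1). Fold changes are on that scale, which understates changes of low genes. Genes with an FPKM of at least 1 in at least 4 of the 12 libraries were kept, which left 11687 genes. All 12 libraries entered 1 model (residual degrees of freedom 9, prior 4.47), with GTWT minus GT, GTD272 minus GT and GTWT minus GTD272 as contrasts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. On simulated data, 47% of genes changed by 0.5 on the log2 scale and 86% of those changed by 1 were recovered for GTWT against GT, with 6 false calls among 11687 genes. These shares were 55% and 87% for GTD272 against GT with 7 false calls, and 47% and 86% for GTWT against GTD272 with 10 false calls.

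Gene lists were tested with camera from limma at a preset correlation between genes of 0.01, over 27 lists and 3 contrasts, adjusted over all 81 tests. On simulated data camera called the shifted list (adjusted p = 3e-14) and 0 of 20 unshifted lists. Genes varied independently in that simulation, so it says nothing about false calls for lists whose members vary together. The correlation estimated from the data was 0.428 for the 2-cell list, above the preset value. The lists hold PP2A subunits, maternal-effect genes, zona and oocyte-secreted factors, oocyte transcription factors, meiotic arrest, CCR4-NOT deadenylation, decapping, exosome and nonsense-mediated decay, translational control, small RNA pathway, DNA methylation and chromatin, DNA damage, p53 targets, meiotic chromosomes, spindle and actin, interferon and RNA sensing, heat shock and unfolded protein response, immediate early genes, 2-cell embryo and MERVL-linked genes, glycolysis, markers of granulosa, theca and blood cells, ribosomal proteins, oxidative phosphorylation, proteasome and histones. A list of mitochondrially encoded genes had fewer than 3 measured members and was not tested. The groups, tests, gene lists, rule for named genes and the alternatives listed first below were fixed before the data were examined.

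Named genes were chosen by rule. Marf1 and Ppp2cb were always named. In each comparison, the 8 largest rises and 8 largest falls were taken among called genes whose 4 libraries of 1 group all lay above the other 4 and whose mean FPKM reached 5 in the higher group, leaving out predicted genes and small RNAs. From each list up to 2 called members with the smallest adjusted p were added. Other list members are named where a list had few called members, and these were chosen after their values were seen.

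Alternatives were a pseudocount of 0.1 or 0.01, other filters, median-of-ratios rescaling, quantile normalization, array weights, a fit of only the groups compared, a replicate block, a 1.5-fold minimum and leaving out each library. Removal of trends on GC content, length and expression, and list tests without each library, were added after the data were seen. GC content and length came from the longest protein-coding transcript in GENCODE M21 and covered 11586 tested genes (99.1%). Files were read and plots drawn in Python 3.11.15. Reads were not used here, and the injected mRNA could not be told apart from the transcript of the trapped gene.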

Results

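MARF1 is a ribonuclease that oocytes need to complete meiosis, and the aspartate mutated here lies in its catalytic NYN domain. RNA of Marf1 gene-trap oocytes (GT) was compared with that of gene-trap oocytes injected with mRNA for wild type MARF1 (GTWT) or for MARF1 with that residue mutated (GTD272), with 4 libraries per group. The relative depth, as a percentage of the deepest library, was 79.5 ± 18.7 in GT (SD, n = 4, range 55.4 to 100), 72.2 ± 7.79 in GTD272 (64.6 to 82.3) and 75.6 ± 8.55 in GTWT (66.1 to 84.2). Between 11167 and 11364 genes reached an FPKM of 1 per library, and Pearson correlations across genes between libraries were 0.951 to 0.981.

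Marf1 (chromosome 16, 14109166 to 14159278, GRCm38) was measured first, since it shows the trap and the injected mRNA. Its FPKM was 1.60 ± 0.242 in GT (SD, n = 4), 9.12 ± 0.806 in GTD272 and 17.5 ± 5.08 in GTWT. Marf1 rose by 2.80 on the log2 scale in GTWT against GT (SE 0.16, adjusted p = 1.73e-06) and by 1.96 in GTD272 against GT (SE 0.16, adjusted p = 5.23e-05), with no overlap between libraries. Marf1 was also 0.84 higher in GTWT than in GTD272 (SE 0.16, adjusted p = 0.0188). That last call was lost without GTD272 replicate 2 (adjusted p = 0.0549), GTD272 replicate 4 (0.0505) or GTWT replicate 4 (0.0547).

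**Figure D1:**
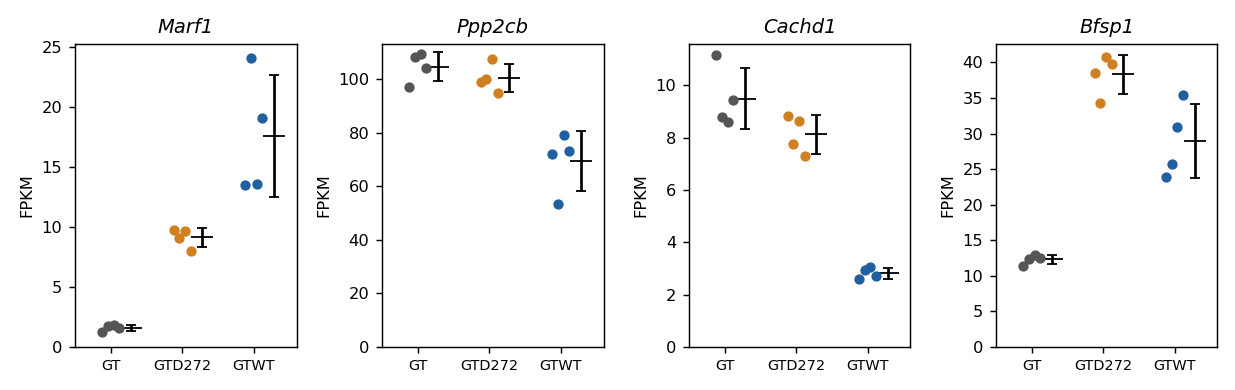
FPKM of Marf1, Ppp2cb, Cachd1 and Bfsp1 in each library of GT, GTD272 and GTWT oocytes, with bars for the mean and SD of 4 libraries. Marf1 lies at 1.60 ± 0.242, 9.12 ± 0.806 and 17.5 ± 5.08 in these groups, Ppp2cb and Cachd1 are lower in GTWT than in both other groups, and Bfsp1 is higher after both injections.

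The comparison of GTWT with GT asks which transcripts change after injection of mRNA for wild type MARF1. Without libraries labelled as control-injected, changes from injection or culture cannot be separated from those due to the protein. Ppp2cb, the beta catalytic subunit of protein phosphatase 2A and a known target of MARF1 (chromosome 8, 33599621 to 33619804, GRCm38), fell from 105 ± 5.57 to 69.4 ± 11.2 FPKM (SD, n = 4), a log2 change of -0.60 (SE 0.10, adjusted p = 0.00142). Ubxn8, listed in the same locus, was at 5.84 ± 0.416 and 6.31 ± 0.904 FPKM and did not pass the test. In all, 1223 genes fell and 717 rose of 11687 tested, with median log2 changes of -0.45 and 0.37. At 2-fold or more, 97 fell and 17 rose.

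The 8 largest falls in GTWT were those of Eno1, Bex6, Tdpoz3, Tdpoz4, Tdpoz5, BB287469, Zfp711 and Dcaf12l1. Zfp711 fell from 10.4 ± 2.67 to 2.25 ± 0.605 FPKM and Dcaf12l1 from 15.6 ± 3.02 to 4.30 ± 0.936 (log2 -1.80 and -1.65), and both genes lie on the X chromosome. Eno1 fell from 5.68 ± 2.76 to 0.000235 FPKM, while its near-identical copy Eno1b was at 20.1 ± 1.69 in GT and 25.7 ± 1.98 in GTWT, so the Eno1 value is uncertain. The Tdpoz genes and BB287469 belong to multi-copy families and are uncertain too. The largest rises besides Marf1 were those of Gstp1, Prm2, Bfsp1, Coro2b, Myoz3, Pnpla3 and Klhdc1, from 1.17 for Gstp1 to 1.03 for Klhdc1 on the log2 scale. Bfsp1, a lens filament protein, rose from 12.3 ± 0.692 to 29.0 ± 5.21 FPKM, and Pnpla3, a lipase of lipid droplets, from 49.1 ± 9.80 to 103 ± 14.9. The call of Bex6 was lost with a pseudocount of 0.01 (adjusted p = 0.0657). That of Tdpoz3 was lost without GT replicate 1 (0.0513) or GTWT replicate 2 (0.0510), that of Tdpoz4 without GT replicate 1, 2 or 3 or GTWT replicate 1, 2 or 4 (0.0514 to 0.0816), and that of Tdpoz5 without GT replicate 1, 2, 3 or 4 or GTWT replicate 1, 2 or 3 (0.0564 to 0.118) and with trends removed (0.0575).

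Genes normally transcribed at the 2-cell stage and linked to the MERVL retrotransposon fell in GTWT as a list (camera adjusted p = 0.00101, adjusted p = 0.632 with an estimated correlation). Of its 21 measured members 11 fell, 1 rose and 9 did not pass (14 fell and 2 rose adjusted over the list alone), with a median log2 change of -1.11. Without GT replicate 1, 3 or 4 or GTWT replicate 1, 2 or 4 the members that fell came to 2, 4, 7, 7, 3 and 4, while camera still passed without any single library (adjusted p = 6.24e-06 to 0.00964). Pramef25 fell from 11.9 ± 3.01 to 4.10 ± 2.25 FPKM and Eif1a from 102 ± 9.20 to 64.0 ± 12.99, and 9 of the other members that fell belong to the Zscan4 and Tdpoz families, whose copies share reads. Sp110 rose by 0.51.

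Among PP2A subunits, Ppp2cb, Ppp2ca and Ppp2r5e fell and 12 of 15 members did not pass (3 fell adjusted over the list alone). The fall of Ppp2ca, of -0.16, was not called after quantile normalization (adjusted p = 0.0932) or with trends removed (0.144). The call of Ppp2r5e was lost without GT replicate 1 or 3 or GTWT replicate 2 (0.0543 to 0.0586) and with trends removed (0.0564). Of 22 CCR4-NOT and maternal decay genes, which shorten poly(A) tails, 6 fell and 16 did not pass (8 fell adjusted over the list alone), and the list did not pass (camera adjusted p = 0.170). Zfp36l2, which binds AU-rich elements and is needed for maternal RNA turnover, fell from 257 ± 10.2 to 144 ± 38.7 FPKM, and the deadenylase Cnot8 from 70.7 ± 6.57 to 52.5 ± 4.15. Of 15 oocyte transcription factors 3 fell and 12 did not pass (2 rose and 5 fell adjusted over the list alone). Tbpl2, the oocyte's TBP paralog, fell from 136 ± 5.25 to 67.9 ± 5.41 FPKM, and Taf4b from 31.6 ± 2.13 to 23.8 ± 2.90.

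Of 13 zona pellucida and oocyte-secreted factors 7 rose, 3 fell and 3 did not pass (7 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0907). Kit, the receptor for KIT ligand, rose from 18.4 ± 1.19 to 32.4 ± 1.66 FPKM, and Astl, the oocyte protease that cleaves ZP2 after fertilization, from 109 ± 1.49 to 183 ± 18.6. Of 17 maternal-effect genes 4 rose and 13 did not pass (6 rose and 1 fell adjusted over the list alone). Nlrp9b and Nlrp2 rose by 0.27 and 0.29. Without GT replicate 3 or GTWT replicate 2 or 4, 2 members rose. The list missed the threshold (camera adjusted p = 0.0506, adjusted p = 0.632 with an estimated correlation) and passed with rescaling (0.0275) and without GT replicate 3 or 4, GTD272 replicate 2, 3 or 4 or GTWT replicate 1 or 3 (0.00937 to 0.0487).

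Of 23 translational control genes 4 rose and 6 fell (4 and 7 adjusted over the list alone), and 13 did not pass. Without GT replicate 1, 2 or 3 or GTWT replicate 2 or 4, 3 fell. Ybx2, an RNA-binding protein that stabilizes stored mRNA, rose from 217 ± 15.5 to 282 ± 11.5 FPKM, and Dazl fell from 478 ± 20.9 to 350 ± 38.4. Of 23 heat shock and unfolded protein genes 7 rose and 4 fell (10 and 5 adjusted over the list alone): Herpud1 rose from 5.62 ± 1.06 to 11.98 ± 2.85 and Ppp1r15a fell from 34.7 ± 4.13 to 22.5 ± 0.284. Of 27 spindle and actin genes 5 rose and 4 fell (6 and 4 adjusted over the list alone), with Tuba1c at 0.42 and Tubb3 at -0.38, and 2 fell without GT replicate 1. Of 10 immediate early genes 3 fell (1 rose and 3 fell adjusted over the list alone), Zfp36 by -0.75 and Ier2 by -0.64. Of 12 interferon and RNA sensing genes Oas1c, Oas1e and Oas1h rose by 0.23 to 0.25 (3 adjusted over the list alone), and these too are near-identical copies. Of 20 glycolysis genes 4 rose and 3 fell (6 and 3 adjusted over the list alone), with Pkm at 0.30.

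Of 28 DNA methylation and chromatin genes 2 rose and 3 fell (the same counts adjusted over the list alone): Dnmt1, the maintenance methyltransferase, rose from 59.7 ± 4.29 to 86.7 ± 5.83 FPKM and the X-linked demethylase gene Kdm6a fell from 19.3 ± 1.80 to 12.9 ± 1.39. Of 28 small RNA pathway genes 3 rose and 1 fell (3 and 1 adjusted over the list alone), with Tdrd1 at 0.48 and Tex19.1 at -0.38. Of 18 meiotic chromosome genes 1 rose and 2 fell (1 and 2 adjusted over the list alone), the cohesin genes Stag2 and Rad21 by -0.57 and -0.27. Of 33 meiotic arrest genes 1 rose and 1 fell (0 and 1 adjusted over the list alone), the latter being Mos at -0.31. Of 23 exosome and nonsense-mediated decay genes 2 rose and 2 fell (2 and 2 adjusted over the list alone), with Exosc2 at 0.77. Of 20 decapping genes Eif4enif1 rose by 0.21 (1 adjusted over the list alone). Of 13 p53 targets 2 rose and 1 fell (3 and 1 adjusted over the list alone), with Sesn1 at -0.62, and of 24 DNA damage genes 3 rose and 1 fell (3 and 1 adjusted over the list alone).

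Of 79 ribosomal protein genes 3 rose and 1 fell, and 0 passed adjusted over the list alone with limma, where 10 had an unadjusted p under 0.05 and 2 were called in the authors' deposited table. Of 85 nuclear oxidative phosphorylation genes 1 rose and 2 fell (0 and 1 adjusted over the list alone), with the assembly factor Ndufaf1 falling from 42.1 ± 3.35 to 23.8 ± 2.70 FPKM. Of 35 proteasome genes 1 rose and 2 fell (1 and 1 adjusted over the list alone), Psmc5 rising by 0.38. Of 54 histone genes limma called Hist1h3h as lower (0 adjusted over the list alone, 6 at an unadjusted p under 0.05, 0 in the authors' deposited table). It was listed at 0 in each GTWT library, and this call was lost without any library but GT replicate 1 (adjusted p = 0.0533 to 0.0980).

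The split between falls and rises in GTWT depended on scaling: 63.0% of the calls were falls as deposited, 49.8% after quantile normalization (976 falls, 984 rises) and 51.2% with GC, length and expression trends removed (907 and 863). The libraries of the groups did not overlap for 21.9% of genes, where chance gives 2.86%. The authors' deposited table calls 1231 lower and 939 higher at a q-value under 0.05, of which 984 and 606 were called here in the same direction and 0 in the opposite.

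The comparison of GTD272 with GT asks what changes after injection of mRNA for the mutated protein. Here too injection and culture cannot be separated from the protein. Ppp2cb did not pass: its FPKM was 105 ± 5.57 in GT and 100 ± 5.33 in GTD272 (SD, n = 4), a log2 difference of -0.06 (95% interval -0.27 to 0.15, adjusted p = 0.796). In GTD272, 165 genes rose and 180 fell, of which 7 and 7 reached 2-fold. Bfsp1 rose from 12.3 ± 0.692 to 38.3 ± 2.80 FPKM, Pnpla3 from 49.1 ± 9.80 to 127 ± 4.18 and Herpud1, a gene of the unfolded protein response, from 5.62 ± 1.06 to 15.1 ± 2.15. The selenoprotein gene Sepp1 fell from 46.6 ± 6.58 to 19.01 ± 2.77, Zfp711 from 10.4 ± 2.67 to 3.71 ± 0.404 and Dcaf12l1 from 15.6 ± 3.02 to 5.98 ± 0.722.

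The other large rises in GTD272 were those of Cdo1, Adcy1, Crym and Draxin, between 1.31 and 0.91 on the log2 scale, and the other large falls those of Eno1, Gsto2, Scimp, Hormad1 and Tifab, between -2.16 and -0.89. Adcy1, an adenylate cyclase, rose from 7.46 ± 1.03 to 15.3 ± 0.954 FPKM. The call of Cdo1 was lost without GT replicate 1 or 2 or GTD272 replicate 1 (adjusted p = 0.0510 to 0.0559) and that of Gsto2 without GT replicate 1, 2 or 3 or GTD272 replicate 1 (0.0523 to 0.0657). That of Scimp was lost without any GT library, GTD272 replicate 1, 2 or 3 or GTWT replicate 2 (0.0552 to 0.128) and with trends removed (0.0625), and that of Hormad1 without any GT library, GTD272 replicate 2 or 4 or GTWT replicate 1 (0.0549 to 0.109) and with trends removed (0.112). The Eno1 call was lost with a pseudocount of 0.01 (0.0961).

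Zona and oocyte-secreted factors rose in GTD272 as a list (camera adjusted p = 0.00119, adjusted p = 0.180 with an estimated correlation). The list's median log2 change was 0.17 here, 0.16 in GTWT against GT, where it did not pass, and -0.01 in GTWT against GTD272. The list means of the libraries overlapped: GT replicate 4 was at 7.45 on the log2(FPKM + 1) scale, above GTD272 replicate 1 at 7.28 and replicate 2 at 7.40. Of 13 members 5 rose and 8 did not pass (6 rose and 1 fell adjusted over the list alone), with a median of 0.17. Without GT replicate 1 or 3 or GTD272 replicate 1 or 3, 3, 2, 3 and 3 members rose. Astl rose from 109 ± 1.49 to 162 ± 12.1 FPKM, Zp3 from 493 ± 36.1 to 619 ± 36.3 and Zp2 from 111 ± 8.48 to 140 ± 7.83, the last 2 being zona proteins. The growth factor gene Gdf9 and Kit rose too. The call of Zp2 was lost without GT replicate 1, 2 or 3 or GTD272 replicate 1, 3 or 4 (adjusted p = 0.0524 to 0.0838) and with trends removed (0.0663), that of Gdf9 without GT replicate 1 or 3 or GTD272 replicate 1, 2 or 3 (0.0540 to 0.0697), after quantile normalization (0.554) and with trends removed (0.236), and that of Kit without GT replicate 3 (0.0509). In the 2-cell list limma called 0 of 21 members in GTD272 (0 adjusted over the list alone, 2 at an unadjusted p under 0.05, 1 in the authors' deposited table), and the list's median was -0.22. Without GTD272 replicate 3 that median turned to 0.13, and without GT replicate 1 or 2 it was -0.07 or -0.36. Of 15 PP2A subunits limma called 0 (1 fell adjusted over the list alone, 3 at an unadjusted p under 0.05, 1 in the authors' deposited table).

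Elsewhere in GTD272, the deadenylase gene Cnot7 fell from 222 ± 14.9 to 166 ± 18.2 FPKM, the only call among 22 CCR4-NOT genes (4 fell adjusted over the list alone). The immediate early gene Zfp36 fell from 25.2 ± 1.93 to 14.6 ± 2.42, the only call of 10 (2 fell adjusted over the list alone). Of 17 maternal-effect genes Ooep and Zar1 rose by 0.25 and 0.29 (3 adjusted over the list alone), but Zar1 did not pass after quantile normalization (adjusted p = 0.364) or with trends removed (0.0523). Of 27 spindle genes Tuba1c rose and Tubb3 fell (2 and 2 adjusted over the list alone), and the Tuba1c call was lost without GT replicate 1, 2 or 3 or GTD272 replicate 1 or 3 (0.0525 to 0.0684) and with trends removed (0.0931). Of 23 heat shock genes Herpud1, Chac1 and Hspa5 rose (6 rose and 4 fell adjusted over the list alone), and the Chac1 call was lost without GT replicate 1 or 3 or GTD272 replicate 1 or 3 (0.0517 to 0.0554). That of Hspa5 was lost without any GT library, any GTD272 library or GTWT replicate 3 or 4 (0.0513 to 0.118). Limma called 0 members of 11 of the lists, among them DNA damage, decapping, meiotic arrest, proteasome and histone genes. Of their 305 measured genes 48 had an unadjusted p under 0.05, 4 passed adjusted over the list alone and 7 were called in the authors' deposited table.

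The counts of GTD272 against GT rested on few libraries. Without GT replicate 1, 2 or 3 or GTD272 replicate 1, 2 or 3 the rises came to 60, 100, 70, 78, 108 and 67, and without GT replicate 1, 2, 3 or 4 or GTD272 replicate 1, 3 or 4 the falls came to 50, 78, 60, 111, 70, 72 and 114. Libraries did not overlap for 12.96% of genes (chance 2.86%), and the authors' deposited table calls 319 higher and 419 lower, of which 139 and 154 were called here.

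GTWT and GTD272, both injected, were then compared directly. These groups differed in the protein supplied and also in the Marf1 level, at 17.5 ± 5.08 against 9.12 ± 0.806 FPKM (SD, n = 4). Ppp2cb was lower in GTWT, at 69.4 ± 11.2 against 100 ± 5.33 FPKM (SD, n = 4), a log2 difference of -0.54 (SE 0.10, adjusted p = 0.0122), and each GTWT library lay below each GTD272 library. In GTWT 215 genes were lower and 73 higher, of which 23 and 2 reached 2-fold. Cachd1 (chromosome 4, 100776679 to 101003749, GRCm38) was at 2.82 ± 0.211 in GTWT and 8.13 ± 0.736 in GTD272, Stk32a, a kinase gene, at 1.97 ± 0.648 and 7.03 ± 0.728, and Zcchc18 at 21.5 ± 3.41 and 45.6 ± 2.53. In GT oocytes these genes were at 9.49 ± 1.16, 6.99 ± 1.11 and 46.3 ± 2.72.

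The other large falls in GTWT against GTD272 were those of Cisd3, AF067063, Adcy1, Emc7 and Zfp367, between -1.16 and -1.04 on the log2 scale. Adcy1 was at 6.87 ± 1.30 FPKM in GTWT and 15.3 ± 0.954 in GTD272, and at 7.46 ± 1.03 in GT. The largest rises were those of Gsto2, St6galnac3, Tifab, Cfap58, Prelid1, Abl2 and Golph3l beside Marf1. Abl2, a tyrosine kinase gene, was at 71.2 ± 5.01 in GTWT and 46.3 ± 3.64 in GTD272. The call of St6galnac3 was lost without GTD272 replicate 2 (adjusted p = 0.0574) and that of Cisd3 without GTD272 replicate 2 or 3 or GTWT replicate 1, 3 or 4 (0.0601 to 0.0779) and with trends removed (0.0571). That of Gsto2 was lost without GT replicate 2 or 3, GTD272 replicate 1, 2 or 4 or any GTWT library (0.0550 to 0.117), and that of Cfap58 without GT replicate 2, any GTD272 library or GTWT replicate 1, 2 or 4 (0.0584 to 0.102).

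The 2-cell and MERVL-linked list was lower in GTWT than in GTD272 (camera adjusted p = 8.50e-05, adjusted p = 0.632 with an estimated correlation), with a median of -0.76. Of 21 members, 2 fell and 19 did not pass (5 fell adjusted over the list alone). The calls of both members, Eif1a and Pramef25, were lost with only these groups in the fit (adjusted p = 0.0681 and 0.0907). The Eif1a call was also lost without GTD272 replicate 1, 2 or 3 or GTWT replicate 4 (0.0501 to 0.0828), and that of Pramef25 without GT replicate 2, 3 or 4, GTD272 replicate 1, 2 or 4 or GTWT replicate 1, 2 or 4 (0.0512 to 0.111) and with trends removed (0.0603). GTD272 replicate 3 had a list mean of 2.61 on the log2(FPKM + 1) scale, near that of the GTWT libraries. Without it the median was -1.11 and 8 members fell.

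Tbpl2 was lower in GTWT, at 67.9 ± 5.41 against 117 ± 16.3 FPKM, and with Gtf2a1l, which partners it in the oocyte, made up the 2 of 15 oocyte transcription factors that fell (2 adjusted over the list alone). The call of Gtf2a1l was lost with only these groups in the fit (adjusted p = 0.0707) and without GT replicate 4, GTD272 replicate 1, 2 or 4 or GTWT replicate 2, 3 or 4 (0.0535 to 0.102) and with trends removed (0.0598). Kit was higher, at 32.4 ± 1.66 against 23.9 ± 0.991, the only call of 13 zona and oocyte-secreted factors (1 rose and 2 fell adjusted over the list alone). Ppp2cb was the only call of 15 PP2A subunits (1 adjusted over the list alone). Of 20 glycolysis genes Pgam1 and the lactate and pyruvate transporter Slc16a1 fell, by -0.30 and -0.64 (1 rose and 2 fell adjusted over the list alone), and without GTD272 replicate 2 both calls were lost (0.0620 and 0.0781), as they were without GTD272 replicate 4 (0.0599 and 0.0602). Without GTD272 replicate 3 or GTWT replicate 2 the call of Pgam1 was lost (0.0508 and 0.0615), and without GTWT replicate 1 or 4 that of Slc16a1 (0.0525 and 0.0524). Limma called 0 members of 19 of the lists, among them CCR4-NOT, maternal-effect, spindle and heat shock genes. Of their 450 measured genes 96 had an unadjusted p under 0.05, 12 passed adjusted over the list alone and 13 were called in the authors' deposited table.

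**Figure D2:**
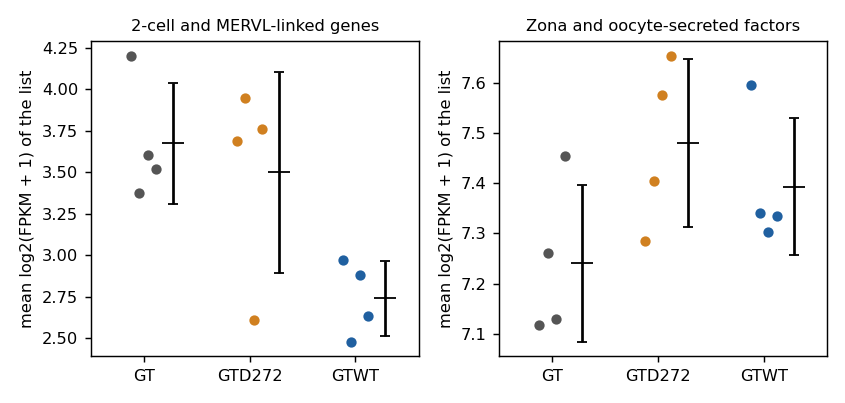
Mean log2(FPKM + 1) over the 21 measured 2-cell and MERVL-linked genes and over the 13 zona and oocyte-secreted factors in each library of GT, GTD272 and GTWT oocytes, with bars for the mean and SD of 4 libraries. For the 2-cell list these means were 3.67 ± 0.364 in GT, 3.50 ± 0.605 in GTD272 and 2.74 ± 0.225 in GTWT, and GTD272 replicate 3, at 2.61, lies among the GTWT libraries. For the zona list GT replicate 4, at 7.45, lies above GTD272 replicate 1 at 7.28 and replicate 2 at 7.40.

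The counts of GTWT against GTD272 also rested on few libraries. Without GTD272 replicate 1, 2, 3 or 4 or GTWT replicate 1, 2 or 4 the higher genes came to 42, 29, 46, 34, 46, 45 and 32, and without GTD272 replicate 1, 2 or 4 or GTWT replicate 2 or 4 the lower genes came to 126, 85, 138, 141 and 118. Of the calls, 74.7% were lower as deposited and 56.0% after quantile normalization (183 lower, 144 higher). Libraries did not overlap for 10.2% of genes (chance 2.86%), and the authors' deposited table calls 176 higher and 434 lower, of which 58 and 176 were called here.

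Genes called in GTWT against GT mostly had the same sign in GTD272. The 717 genes that rose had a median log2 change of 0.20 in GTD272, 95.3% with the same sign, and the 1223 that fell one of -0.20, 93.0% with the same sign. The shared GT libraries raise these shares: with GTD272 simulated as unchanged, 63.6% and 60.9% had the same sign, with medians of 0.03 and -0.03. For genes called against 2 GT libraries and read against the other 2, the shares were 89.4% (86.9% to 92.3% over 6 splits) and 89.2% (87.2% to 92.2%), with medians of 0.21 and -0.20. Of the 165 genes that rose in GTD272, 127 also rose in GTWT, where independent lists share 10.1, and of the 180 that fell 146 also fell, where independent lists share 18.8. Both comparisons use the GT libraries. With these split 2 and 2, the rises shared 21.2 genes on average (range 11 to 36, independent 0.871) and the falls 21.8 (10 to 36, independent 1.52). With no effect simulated 0 were shared, but these simulations called at most 0.04 genes per list on average, so the value says little.

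Across the 11687 genes the fold changes of both injections correlated with Pearson r of 0.614 and Spearman rho of 0.645, where unchanged groups simulated against the same GT libraries gave 0.511. The covariance was 0.0542 against a simulated 0.0264, a difference of 0.0278, and with the GT libraries split r was 0.272 (0.167 to 0.338). Genes are not independent replicates, so no p-value is given. Of the 215 genes lower in GTWT than in GTD272, 194 were also lower in GTWT than in GT, where independent lists share 22.5 and a split of the GTWT libraries gave 74.2 (25 to 153, independent 6.59).

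**Figure D3:**
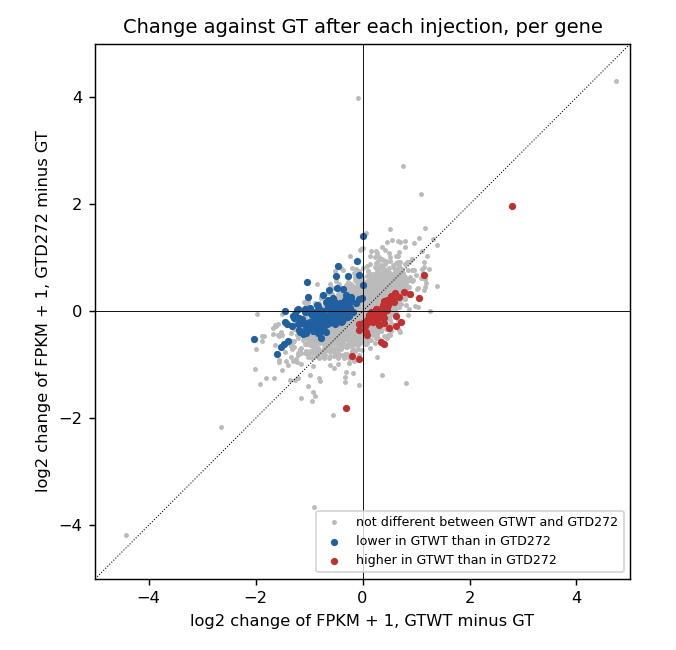
Log2 change of FPKM + 1 of each tested gene in GTWT minus GT (horizontal) and GTD272 minus GT (vertical), with genes lower (215, blue) and higher (73, red) in GTWT than in GTD272 marked, and a dotted line where both changes are equal. Most blue points lie left of the vertical axis and near 0 on the other. The small nucleolar RNA Snora47, at 7.99 on the vertical scale, lies outside the plot.

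Over the 1300 most variable genes, libraries correlated with r of 0.593 within groups and 0.582 between groups, a difference of 0.0106 (exact permutation p = 0.253, one-sided, over each split of the libraries into groups of 4). Over all genes reaching an FPKM of 1 these values were 0.968 and 0.964 (exact permutation p = 0.000693). Hierarchical clustering of the libraries over these genes into 3 clusters did not return the groups. Each GTD272 and GTWT library shared a cluster with GT replicate 4. The first principal component (18.6% of the variance) had the GT libraries on the negative side and the GTWT libraries on the positive side.

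Of 25 granulosa and cumulus markers 19 had a mean FPKM under 1 in each group, of 17 theca markers 14 and of 19 blood and endothelial markers 16. Some markers, chosen after their values were seen, were not low in GT, GTD272 and GTWT: Serpine2 at 97.0, 102 and 103 FPKM, Kitl at 14.4, 12.9 and 12.7, Pecam1 at 10.3, 10.8 and 10.4, C1qb at 11.2, 10.6 and 12.7, and Cyp19a1 at 4.87, 5.04 and 6.67. Nr5a2, which oocytes in this table hold at over 100 FPKM, fell from 125 ± 4.04 in GT to 103 ± 3.09 in GTWT and was at 109 ± 3.30 in GTD272. It was the only call among 6 measured granulosa markers in GTWT and in GTD272 against GT (1 in each adjusted over the list alone), and the GTD272 call was lost after quantile normalization (adjusted p = 0.0704), with trends removed (0.337) and without any GT library, any GTD272 library or GTWT replicate 1 (0.0505 to 0.109). Tek was the only call of 3 measured blood markers, at 3.103 ± 0.685 in GT and 4.59 ± 0.627 in GTWT, a call lost without GT replicate 1 or 3, GTD272 replicate 1, 2 or 3 or any GTWT library (adjusted p = 0.0529 to 0.132). Of 3 measured theca markers limma called 0 in any comparison, 0 had an unadjusted p under 0.05 and 0 were called in the authors' deposited table.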

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

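The tests of other splits, of the shared GT libraries, of Ppp2cb under a common ratio, of the share of X-linked genes, of summed gene families, of oocyte pools and of injection itself were chosen after the results were seen, as was the removal of trends.

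Among the 35 ways to split the 8 libraries of a comparison 4 against 4, only 1 split, the real one, gave as many genes in each comparison. The real groups gave 1940 genes for GTWT against GT, where the highest other split gave 2. They gave 345 for GTD272 against GT (highest other 1) and 288 for GTWT against GTD272 (highest other 2). A share of 1 in 35 is the smallest these splits can give. It argues against a chance assignment of these libraries to the groups as the source of the counts. If the samples of a group are technical, the splits cannot exclude differences between single pools or batches.

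Genes called in GTWT oocytes mostly had the same sign and a smaller median change in GTD272 oocytes (0.20 against 0.37 for rises, -0.20 against -0.45 for falls), with exceptions such as Bfsp1, at 1.56 in GTD272 and 1.16 in GTWT, and Pnpla3, at 1.38 and 1.06, whose direct differences did not pass (adjusted p = 0.0667 and 0.211). The genes were chosen on their change in GTWT, which enlarges the GTWT medians, so part of the gap would arise with equal effects. The ratios given below were measured on GT and GTWT libraries left out of the choice of genes. Chance values of the shared GT libraries cannot be the whole cause, since with these libraries split 2 and 2 the covariance of the fold changes averaged 0.0301 (SD 0.0055 over 6 splits, lowest 0.0198). Less injected mRNA in GTD272, acting in proportion on every gene, would give 1 ratio between both effects. The spread around a common ratio of 0.435 was 1.54 in units of the replicate variance, against 0.755 at most in 50 simulations with 1 ratio. The ratio was 0.702 for genes that rose and 0.369 for genes that fell. These values argue against a smaller dose acting in proportion on every gene, on the log2(FPKM + 1) scale, as the only cause. A smaller dose whose effect differs between genes would not give 1 ratio, so the test cannot exclude it. The simulations gave each gene independent noise, which real libraries need not have. A smaller dose together with an effect shared by both injections was not tested and stays open. For Ppp2cb taken by itself, a smaller dose as the only cause stays open: the common ratio predicts -0.26 in GTD272 and that of genes that fell -0.22, both inside the observed interval of -0.27 to 0.15. The Marf1 excess over GT in GTD272 was 0.472 of that in GTWT, measured in FPKM. The common ratio of 0.435 was measured on log2 changes, so it cannot be set against this value. With 0 libraries of GT oocytes labelled as injected with another RNA, injection and handling cannot be told apart from residual activity of the mutated protein, and both may contribute.

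X-linked genes were lower in both injected groups. Of 402 X-linked genes 77 (19.2%) fell in GTWT against GT, where 10.2% of autosomal genes did (odds ratio 2.10, Fisher's exact adjusted p = 3.56e-07), and the mean X minus autosome level fell from -0.34 ± 0.0231 to -0.50 ± 0.0197 (log2, SD, n = 4, exact p = 0.0286, the smallest possible, adjusted 0.0429, no overlap). Removing trends on GC, length and expression left a difference of -0.11 (GTWT minus GT, -0.16 before, pooled SD 0.0215 before and 0.0136 after). Leaving out multi-copy families, found by a shared stem of their gene names, left -0.15. The exact p was 0.0286, the smallest possible, in both settings. Predicted genes named Gm were kept by that rule, so copies among them may remain. Of X-linked genes 65.7% lay below the autosomal median change (95% interval 60.8% to 70.3%). These values argue against trends, multi-copy families found by name or a few X-linked genes as the whole cause in these libraries. Since genes are not independent replicates, the Fisher p-value and the interval describe the genes, not the spread between samples. Before removal of trends, the X minus autosome difference was -0.12 in GTD272 against GT and -0.03 between GTWT and GTD272 (exact p = 0.0857), so an effect of injection or culture shared by both groups may account for it as well as MARF1 itself, which 0 control-injected libraries leave open.

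The 2-cell and MERVL-linked list was lower in GTWT (camera adjusted p = 0.00101, adjusted p = 0.632 with an estimated correlation). Reads shared between near-identical copies can make 1 change look like several. With all libraries, limma argues against this as the whole cause: with the copies in the list summed it called 4 of 9 families lower in GTWT than in GT and 1 higher. Exact tests of these sums passed 0 of 9 after adjustment (smallest adjusted p 0.0514, from an unadjusted 0.0286 that 4 libraries against 4 cannot go below). The log2 changes of the lower families were -1.24 for Zscan4 (adjusted p = 0.0240), -2.08 for Tdpoz (0.0173), -1.41 for Pramef25 (0.00437) and -0.68 for Eif1a (0.00260). Pramef25 and Eif1a enter as 1 gene each, which summing left unchanged, and the multi-copy families Tcstv (-0.02, limma adjusted p = 0.953) and Usp17l (-0.45, 0.290) did not pass. Without GT replicate 1 the calls of Zscan4 and Tdpoz were lost (0.0746 and 0.0561). That left 2 families lower, too few by the rule used here, so the argument against shared reads rests on that library. The Tdpoz call was also lost without GTWT replicate 2 (0.0534) and that of Zscan4 without GTWT replicate 4 (0.0643), while Pramef25 and Eif1a kept theirs without any single library. Oocyte pools that differ in this list whatever their group cannot be told apart from an effect of active MARF1, and both stay open: the exact p of the list mean was the smallest possible, 0.0286, but beside 0.714 and 0.114 in the other comparisons its adjusted value of 0.0857 could not have passed and decides neither way.

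A library lying far from the other 3 of its group was found for 15 of 318 groups of values tested (4.72%), where chance gives about 5%. Pnpla3 was at 80.5 FPKM in GTWT replicate 1, with 108 to 111 in the others. Eno1 was at 2.96 FPKM in GTD272 replicate 3, with 0.000232 to 0.000242 in the others, and at 0.000241 in GTWT replicate 1, with 0.000233 to 0.000234 in the others. Tdpoz3 was at 31.3 FPKM in GT replicate 1 (9.94 to 10.98 in the others) and Zfp711 at 14.3 in GT replicate 1 (8.75 to 9.51) and at 4.32 in GTD272 replicate 2 (3.48 to 3.59). Eif4enif1 was at 123 FPKM in GT replicate 2 (114 to 115), Ybx2 at 245 in GTD272 replicate 4 (267 to 271), Dazl at 417 in GTD272 replicate 2 (375 to 379) and Tuba1c at 211 in GTD272 replicate 4 (208 in the others). Ndufaf4 was at 58.0 FPKM in GTD272 replicate 1 (50.4 to 51.6) and Emc7 at 12.1 in GTWT replicate 3 (14.3 to 14.6). In GT replicate 2, 11277 genes reached an FPKM of 1 (11256 to 11258 in the others), the FPKM sum without small RNA was 400611 in GTWT replicate 2 (404216 to 404939), and the X minus autosome level was -0.50 in GTD272 replicate 1 (-0.46 to -0.45).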

How the results depend on the processing

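The removal of GC, length and expression trends and the list tests without each library were chosen after the data were seen. No call of a named gene changed direction under any alternative, but the balance of rises and falls did. For GTWT against GT, rises outnumbered falls after quantile normalization (984 and 976). For GTD272 against GT, they did so with rescaling (172 and 167), quantile normalization (155 and 150), the replicate block (99 and 95), trends removed (137 and 114) and a 1.5-fold minimum (35 and 30). The same held without GT replicate 1 (60 and 50), 2 (100 and 78), 3 (70 and 60) or 4 (113 and 111) or GTD272 replicate 1 (78 and 70), with 114 each without GTD272 replicate 4. The cause was not tested. Of 130 calls of named genes, 78 held in each setting apart from the 1.5-fold minimum, 52 were lost in at least 1 setting (46 of them without some library) and 58 were under 1.5-fold.

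For GTWT against GT, leaving out 1 library gave 483 to 726 rises and 845 to 1216 falls, and a 1.5-fold minimum gave 122 and 380. For GTD272 against GT, leaving out 1 library gave 60 to 168 rises and 50 to 207 falls, with the lowest without GT replicate 1, the shallowest library. That comparison gave 35 and 30 with a 1.5-fold minimum, 102 and 107 with no filter, and 114 falls with trends removed. For GTWT against GTD272, leaving out 1 library gave 29 to 70 higher and 85 to 246 lower genes, with the lowest without GTD272 replicate 2. It gave 12 and 109 with a 1.5-fold minimum, 27 and 97 with only these groups in the fit, 144 higher after quantile normalization and 125 lower with no filter. Fewer libraries leave less power and a fold minimum removes calls by construction. For the other settings the cause was not tested.

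The replicate numbers did not pair the libraries: 2 of 12 same-number pairs correlated above 0.1 (range -0.222 to 0.211) and 3 of 12 libraries were closest to their own number. With a replicate block the fit called 608 rises and 1091 falls for GTWT against GT, 99 and 95 for GTD272 against GT, and 38 and 149 for GTWT against GTD272.

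Over all genes, libraries correlated slightly more within groups than between them (r of 0.968 and 0.964, exact permutation p = 0.000693). So they did by Spearman correlation over the most variable genes (rho of 0.656 and 0.627, exact permutation p = 0.000346), where Pearson correlation gave 0.253. The cause of this difference was not tested. Hierarchical clustering of the libraries into 3 clusters did not return the groups in any of these settings. The correlation of fold changes fell to 0.272 with the GT libraries split. The split removes chance values of single GT libraries, but no offset common to them, and leaves fewer libraries. List tests made 0 calls with an estimated correlation (lowest adjusted p 0.180), against 3. That correlation was 0.428 for the 2-cell list, above the preset 0.01, and 0.004 for zona factors, below it. A correlation above the preset can thus not account for the loss of the zona call. With trends removed the list tests made 5 calls, with the cause not tested. The added calls were zona factors (adjusted p = 0.0478) and maternal-effect genes (0.0122) in GTWT against GT, and the latter were also called with the block (0.0181), with rescaling (0.0275) and without any of 7 libraries (0.00937 to 0.0487). Leaving out 1 library gave 3 to 5 list calls, with 5 without GTD272 replicate 2, where ribosomal proteins passed as higher in GTD272 than in GT (0.0371, 0.148 with all libraries). Of 60 list counts of 3 or fewer calls, 40 moved by over 1.5 times without some library, and of 12 larger ones 5 did. Relative depth was 55.4% to 100% within GT, and 47% to 55% of simulated genes changed by 0.5 on the log2 scale were recovered, so changes of this size can be missed.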

Other observations

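The zinc finger and held-out observations in this part were chosen after the values were seen, as was the look at GC content.

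Zinc finger genes named Zfp fell more often than others in GTWT oocytes. Of 283 measured, 47 fell and 11 rose against GT, a share of falls of 16.6% where 10.3% of other genes fell (odds ratio 1.73, Fisher's exact adjusted p = 0.00455). With trends removed the odds ratio was 1.70 (adjusted p = 0.0194). In GTD272 against GT 9 fell (odds ratio 2.16, adjusted p = 0.0642, and 0.757 with trends removed), and 8 were lower in GTWT than in GTD272 (odds ratio 1.57, adjusted p = 0.255, and 0.0221 with trends removed). Genes are not independent replicates, so these p-values describe the lists of calls.

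Genes lower in GTWT than in GTD272 lay near the GT level in GTD272 on average. This does not hold for each gene, since Adcy1, given above, was higher in GTD272 than in GT. With 200 genes chosen on 2 GTD272 libraries and measured on the other 2, over 6 such splits, held-out GTD272 libraries differed from GT by -0.08 on average on the log2 scale (-0.14 to 0.0013), while GTWT lay -0.65 from the held-out GTD272 libraries and -0.73 from GT. The GTWT libraries took part in the choice, so both of these values overstate the difference.

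Fold changes against GT followed the GC content of transcripts. Across 11586 genes the Spearman correlation of fold change with GC was 0.215 for GTWT, 0.261 for GTD272 and 0.0231 for GTWT against GTD272. Genes that fell in GTWT had a median GC content of 46.3%, those that rose 51.8% and all genes 49.7%. The slope on GC per library was 0.0367 ± 0.0472 in GTWT, 0.0218 ± 0.0461 in GTD272 and -0.0585 ± 0.0330 in GT (log2 per 10 points of GC, SD, n = 4, exact p = 0.0571 for either injected group against GT and 0.686 between them). With trends removed, 599 rises and 829 falls of GTWT against GT remained among 863 and 907 calls.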
